A study of Homo sapiens with 23 samples.

How the data were processed

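The samples were single cells of 3 human lines: 11 scMAT-seq libraries of hiPSC (4 at 20 h and 4 at 48 h of 3D culture with BMP4, and 3 that held untreated cells and cells given CHIR99021), 3 scRNA-seq libraries at 36 h, H9 libraries (2 fresh and 2 frozen by scMAT-seq, 1 scMspJI-seq, 1 bead test and 1 of bulk DNA stripped of protein) and 2 HEK293T libraries. Per the submitters' processing notes, reads were split with bcl2fastq 2.20 and mapped with BWA 0.7.15 to hg19, and all positions here are on hg19. The version of any other program is not given in the sources used here.

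The deposited transcript tables hold expected count values per gene and cell, since the authors corrected the number of distinct 4-base barcodes (UMIs) for barcodes drawn more than once: 1 barcode is listed as 1.002, 10 as 10.2 and 100 as 126.8. Of the values above 0, 75.11% equal such a corrected whole number, and 6.334% lie below 0.95, where reads were split between genes, and hold 0.512% of the total. The authors' sheets hold count values per cell, of transcripts and of calls, and transcripts matched the tables within 1 in 1632 of 1632 cells. For GpC calls 1296 of 1392 cells matched and for WCG calls 1392 of 1488. All others were in the H9 frozen libraries, whose files held a median of 1.084 and 1.083 times the calls of the sheet. The deposited call lists hold other values, deduplicated calls by cell, chromosome, strand and position, and the authors' lists of cell status and cell type are labels. Calls at WCpA and WCpG came from the authors' sheets.

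Cells were kept as the authors' status list marks them: of 1848 wells 36 were marked as used in no analysis, and 1057 cells were kept for RNA, 931 for WCG and 840 for GpC. In the mixed libraries cells 1 to 48 were untreated and 49 to 96 treated. The tables held 19387 rows, of which 92 were spike-ins. Expected counts were summed over the cells of a library and arm and rounded to whole numbers, so that the library was the replicate. After rounding, totals ran from 1017171 to 1577698 for CHIR99021, 1340858 to 2314611 for 48 h against 20 h, 1340858 to 3491552 for 36 h against 20 h, 1017171 to 2133850 for 20 h against untreated cells and 251976 to 888082 for H9. Values with no sum over cells, such as calls per cell, were averaged by library.

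Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The p-values measure spread between libraries, which may be technical as well as biological. By the titles, the libraries of each BMP4 time share a plate or experiment, as do those with CHIR99021 and each H9 scMAT-seq group. The p-values therefore do not measure spread between separate experiments. Fixed lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated one. Calls in bins of 10 kb (GpC) and 100 kb (WCG) were tested with edgeR with the total of calls as library size. Per-cell values were compared by exact two-sided permutation of libraries, or by sign flips where cell types of the same library were compared. Untreated and CHIR99021 cells were compared by permutation, without pairing the arms of a library. Cell types were those of the authors, with at least 5 cells of a type in a library, and were set against the other types of the same libraries. DESeq2 1.42.0 was the alternative test. Other steps used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

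The comparisons, tests, most alternatives and the rule for naming genes were chosen before the data were examined. Named were the 10 largest rises and falls among genes that passed, whose libraries did not overlap and whose higher group reached 20 CPM, and for each list the 3 members that passed with the largest change, or the member with the highest mean where none passed. Spike-ins and genes that tell sex were left out of this ranking. Near-identical copies were to be left out as well and were recognised as the 2636 genes with over 50% of their total in split values, so that copies below this share, the SNAR-A genes among them, stayed in. For bins 5 each way were named, and for HEK293T against H9, which have 1 and 4 libraries, 8 each way from 50 CPM without a test. Against groups at 0 the fold was taken to a floor of 3 counts over the group, and with 1 to 3 counts a 95% counting interval is given.

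The 19 lists held these numbers of genes, with those in the tables before the "of": pluripotency 28 of 28, streak 31 of 32, later mesoderm 25 of 28, endoderm 20 of 21, germ cell 22 of 23, amnion 28 of 29, neural ectoderm 18 of 18, trophoblast 12 of 15, epithelial to mesenchymal transition 19 of 19, WNT targets 23 of 23, BMP targets 20 of 20, DNA methylation 19 of 20, naive pluripotency 15 of 15, cell cycle 28 of 28, stress 20 of 20, mitochondrial 0 of 15, blood and endothelium 14 of 15, fibroblast 15 of 15 and glycolysis and hypoxia 25 of 25. As 0 mitochondrial genes were in the tables, that list was not tested. Some genes are in several lists, so that the calls of these lists are not independent. Among them are T and SP5 (streak and WNT targets), GATA4 and GATA6 (later mesoderm and endoderm) and HAND1 (later mesoderm, amnion and BMP targets). The trophoblast, naive and blood lists had too few measured genes to test with CHIR99021.

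That untreated and treated arms of a numbered library belong together was checked on 7353 genes: after removing the arm means, the same library correlated at 0.188, 0.247 and 0.176 and different libraries at -0.144 to -0.047. The numbers of the BMP4 libraries were not taken as pairs. The fits were tested on simulated data with 100 changed genes. They found 69%, 76%, 72%, 76%, 69% and 27% of 2-fold changes (CHIR99021, 48 h against 20 h, 36 h against 20 h, 48 h against 36 h, 20 h against untreated, H9) and 96%, 96%, 98%, 99%, 100% and 82% of 4-fold changes, with 7, 13, 7, 11, 10 and 3 wrong calls. For bins, 34% and 62% of 2-fold GpC changes and 99% of 2-fold 5mC changes were found with CHIR99021 and at 48 h. Of changes of log2 0.5, 0% and 1% were found for GpC and 68% and 90% for 5mC. In a further simulation of 48 h against 20 h, fits without each library's trend against calls in stripped DNA made 64 wrong GpC and 297 wrong 5mC calls. Fits with this trend made 6 and 8.

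Alternatives were the test, the scaling, the count filter, the cells kept, cells thinned to 5000 UMIs, the library as a block, bin size, summary over cells, each library left out, and, added after the data were seen, fits without Neuroectoderm-like cells, with each library's trend against calls in stripped DNA, and with autosomes scaled to their own totals. The ratio of WCpA to WCpG was also added after the data were seen. Promoters, transcription start sites and links of expression with promoter state were not analysed here, as the annotation used here is on another build, and bins took their place.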

Results

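The series measured methylated cytosine (5mC), open chromatin and messenger RNA in single human cells. HEK293T is a kidney-derived line, H9 is an embryonic stem cell line, and AICS-0024 is an induced pluripotent stem cell (hiPSC) line. In scMAT-seq all 3 layers come from the same cell. A restriction enzyme cuts beside 5mC, so that methylated sites alone are seen, and a methyltransferase marks GpC in open chromatin. The 23 samples held 4 scMAT-seq libraries of hiPSC grown as 3D colonies with 5 ng/ml BMP4 for 20 h, 4 for 48 h, and 3 libraries of 36 h that were read by scRNA-seq alone. A further 3 libraries each held untreated hiPSC in cells 1 to 48 and hiPSC given 5 uM CHIR99021 for 24 h, an inhibitor of GSK3 that turns on WNT signalling, in cells 49 to 96. H9 gave 2 fresh and 2 frozen scMAT-seq libraries, and the remaining samples were 1 each of H9 scMspJI-seq (5mC alone), an H9 test of beads, H9 bulk DNA stripped of protein, HEK293T scMAT-seq and HEK293T scMA-seq (no RNA).

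Cells kept per library numbered 43 to 53 at 20 h, 72 to 86 at 36 h, 61 to 71 at 48 h, 36 to 40 with CHIR99021 and 28 to 32 untreated. Transcripts per library, summed over cells, ran from 1341358 to 2134444 at 20 h, 3003564 to 3492101 at 36 h, 1388439 to 2315224 at 48 h, 1040157 to 1578291 with CHIR99021 and 1017710 to 1106401 untreated. The H9 libraries held 252316 and 639962 fresh (14 and 47 cells) and 888640 and 853533 frozen (35 and 30 cells), and HEK293T held 478979 (31 cells). The 5mC calls at WCG per library ran from 4128071 to 6753149 at 20 h, 6688294 to 7957115 at 48 h, 3510191 to 4456441 with CHIR99021 and 2992432 to 4147272 untreated. The GpC calls ran from 4922543 to 7725410, 9104298 to 11531734, 5243812 to 6643146 and 4320266 to 5717328 in the same order. The H9 libraries held 1049154 to 3208567 WCG and 1367035 to 4920635 GpC calls. HEK293T held 2222240 and 5738761 by scMAT-seq and 2049708 and 8861642 by scMA-seq, and H9 scMspJI-seq held 1337079 WCG calls.

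The comparison of CHIR99021 with untreated hiPSC asks what a day of WNT activation does to pluripotent cells. Genes of the primitive streak, from which mesoderm and endoderm arise, rose together with WNT targets. T and SP5, which rose, are in both lists. Several genes of the pluripotent state fell, and enzymes and regulators of glycolysis rose. Of 9826 genes tested over 3 libraries against 3, 448 changed in edgeR (238 in DESeq2, and 63 with every cell thinned to 5000 UMIs), 247 up and 201 down. Of 11 measured genes of the primitive streak and nascent mesoderm, 6 rose and 0 fell, and 7 passed when adjusted over the list alone. EOMES, a T-box factor of early mesoderm and endoderm, rose from 1.28 ± 0.569 to 27.96 ± 6.19 CPM (SD, n = 3 each), a log2 fold change of 4.37 (SE 0.457, edgeR adjusted p = 2.78e-06). T, which encodes brachyury, rose by 3.99 (SE 0.563, adjusted p = 0.000128) to 22.2 ± 11.2 CPM, and NODAL, a signal that induces mesendoderm, by 3.05 (SE 0.198, adjusted p = 2.69e-09), from 22.2 ± 8.94 to 183 ± 18 CPM. Of 13 measured WNT target genes 6 rose and 0 fell (8 adjusted over the list alone). Among them were SP5, a transcription factor induced by WNT, at 3.017 (SE 0.187, adjusted p = 2.23e-09), and DKK1, a secreted WNT inhibitor, at 2.94 (SE 0.469, adjusted p = 0.000453). SP5 rose by 5.29 in the cells that the authors did not name Neuroectoderm-like and by 1.27 in those that they did, from 7.05 to 280 CPM in the former and from 107 to 257 CPM in the latter. The former were typed IPSC when untreated and, but for 1 cell, 24 Hr +CHIR when treated. As the types were called on the same RNA, this difference is not independent of the typing. APCDD1, another WNT inhibitor, rose by 2.56 (adjusted p = 0.0015, and 0.0643 without library 4).

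Of 7 measured genes of definitive endoderm 2 rose and 0 fell (2 adjusted over the list alone). FOXA2, a factor of endoderm and node, had 3 counts in untreated cells and rose 21.1-fold (95% counting interval 6.95 to 105, adjusted p = 0.000656), and FOXH1, a partner of SMAD proteins, rose by 0.59 (adjusted p = 0.025). Of 22 measured genes of glycolysis and hypoxia 8 rose and 1 fell (16 adjusted over the list alone). PDK1, a kinase that holds back pyruvate dehydrogenase, rose from 4.14 ± 0.325 to 30.99 ± 3.91 CPM (log2 2.85, adjusted p = 1.28e-05) and BNIP3, a mitochondrial mitophagy receptor, from 33.1 ± 5.25 to 169 ± 21.1 CPM (log2 2.37, adjusted p = 8.38e-09), while ADM, which encodes adrenomedullin, fell by 2.17 (adjusted p = 1.25e-05). The other large rises were LOC644189, at 33.2 ± 6.18 CPM with 0 counts in untreated cells (at least 33.9-fold), LOC284412, with 2 counts in untreated cells (36.5-fold, counting interval 9.79 to 306), and CDA, a cytidine deaminase, at 2.95 (adjusted p = 2.67e-05). The folds with a counting interval are ratios of counts summed over libraries, the intervals cover counting error only, and the "at least" values set the group at 0 counts to 3 counts and take the other group as measured.

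Of 25 measured genes of pluripotency and epiblast 1 rose and 8 fell (13 adjusted over the list alone). GDF3, a TGF-beta family ligand, rose by 2.28 (adjusted p = 6e-04). PRDM14, a repressor that keeps the pluripotent state, fell from 24.0 ± 2.83 to 6.58 ± 3.5 CPM (log2 -1.84, adjusted p = 0.00215), TERF1, a telomere protein, from 632 ± 135 to 241 ± 35.1 CPM (log2 -1.39, adjusted p = 1.39e-06), and DNMT3B, a de novo DNA methyltransferase, from 452 ± 4.31 to 231 ± 32.7 CPM (log2 -0.96, adjusted p = 1.9e-05). DNMT3B was the only one of 13 genes of the DNA methylation machinery to pass (3 adjusted over the list alone), and PRDM14 and PDPN (-0.83, adjusted p = 0.00246) were the 2 of 6 germ cell genes that fell (2 adjusted over the list alone). The largest falls outside the lists were PPP1R17 (-2.35), DHRS3, a retinal reductase (-2.21), SORBS2 (-2.16), CHGA (-2.04), LIMCH1 (-1.92), TRIML2 (-1.87), CYR61, a matrix protein (-1.81), and GPR176, an orphan receptor (-1.76), with adjusted p from 7.34e-06 for GPR176 to 0.0115 for LIMCH1. The call of LIMCH1 ended without library 2 (-1.23, adjusted p = 0.247) or library 3 (-1.78, adjusted p = 0.0826), and that of PPP1R17 without library 4 (-2.25, adjusted p = 0.051).

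Fewer members moved in the other lists. Of 14 neural ectoderm genes 1 rose (PAX3, 2.06) and 1 fell (SIX3, -1.39), of 8 BMP targets 2 rose (ID2, 1.38, and MSX1, 0.79), of 6 amnion genes 1 rose (HEY1, 2.21), and of 6 later mesoderm genes 1 rose (MSX1). Of 12 genes of the epithelial to mesenchymal transition 1 rose (MMP2, 1.02) and 1 fell (CLDN6, -0.45). Of 27 cell cycle genes 3 rose, CDKN1A (0.99), CCND1 (0.65) and CDK1 (0.54) with adjusted p = 0.0066, 0.0013 and 0.037, and 1 fell (6 adjusted over the list alone). Of 12 stress genes 1 rose and 2 fell, HSPA8 by 0.58 and ATF4 by 0.41, and of 10 fibroblast genes 1 fell, THY1, by 0.91. PTN, of the trophoblast list, did not pass (-0.69, adjusted p = 0.0595).

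Several of these calls ended when 1 library was left out, in fits with fewer libraries and without the library as a block. Without library 2, adjusted p was 0.0746 for MSX1, 0.181 for FOXH1, 0.0821 for HEY1, 0.063 for CLDN6, 0.138 for CDKN1A, 0.0761 for CDK1 and 0.193 for ATF4. Without library 3 it was 0.0674 for MSX1, 0.15 for FOXH1, 0.0517 for PAX3 and 0.106 for CDK1. Without library 4 it was 0.156 for MSX1, 0.0781 for FOXH1, 0.0581 for PDPN, 0.184 for HEY1, 0.0519 for PAX3, 0.0741 for MMP2, 0.2995 for CLDN6, 0.107 for CDKN1A, 0.336 for CDK1 and 0.327 for ATF4.

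Camera called the streak (adjusted p = 1.2e-33), WNT (1.93e-12), glycolysis (4.95e-12) and pluripotency (5.38e-10) lists with a preset correlation. These held with adjusted p = 0.00687, 0.0225, 0.0292 and 0.0152 with an estimated correlation. The calls of DNA methylation and of stress (adjusted p = 0.0322 each, both down) were lost, at adjusted p = 0.164 and adjusted p = 0.414 with an estimated correlation. In 3 lists that did not pass, the median, the mean and the test differed in sign: germ cell (median 0.01, test down), amnion (median -0.06, test up) and epithelial to mesenchymal transition (mean 0.05, test down). In the 4 splits of the libraries that part as many pairs, the highest count besides the real one was 0, with too few splits for a share under 0.05. Fitting the library as a block, since each library held both arms, gave 832 changed genes in place of 448. The count fell to 150 without library 4 and to 261 without library 2. Neuroectoderm-like cells made up 46.2% ± 5.7 of treated and 39.1% ± 10.7 of untreated cells (SD, n = 3 each). Without them 364 genes changed, with 6 of 8 streak genes and 3 of 8 WNT targets up and 8 of 25 pluripotency genes down. As the types were called on the same RNA, the cells left in each arm were chosen on that RNA as well.

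The comparison of 20 h of BMP4 with untreated hiPSC asks what the first day in 3D culture changes. Genes of the amnion, targets of BMP and genes of the streak rose, and neural genes fell. Of 10445 genes tested (4 libraries against 3), 567 changed, 253 up and 314 down. Of 10 measured genes of amnion and surface ectoderm 7 rose and 0 fell (8 adjusted over the list alone). TFAP2A, a factor of surface ectoderm, stood at 67.7 ± 4.03 CPM against 0 counts (at least 70.7-fold), and GATA2 at 8.91 ± 2.6 CPM against 0 counts (at least 9.39-fold). GATA3, a factor of amnion and trophoblast, had 2 counts in untreated cells and rose 68.1-fold (counting interval 18.7 to 565). CDX2, a caudal homeobox factor, had 1 count and rose 70.4-fold (12.4 to 2798). Of 14 measured BMP targets 10 rose and 0 fell (12 adjusted over the list alone), with MSX2 at 4.25 and GATA2 and GATA3 counted here as well. BAMBI, a decoy receptor of BMP, rose by 3.45 (SE 0.246, adjusted p = 9.01e-09), from 10.7 ± 1.11 to 117 ± 24.3 CPM.

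Of 12 measured streak genes 5 rose and 1 fell (6 adjusted over the list alone), with EOMES at 5.54 (SE 0.446, adjusted p = 5.26e-08; 62.8 ± 17.7 against 1.26 ± 0.56 CPM) and T at 4.86 (SE 0.402, adjusted p = 6.95e-08). Of 13 WNT targets 4 rose and 2 fell (10 adjusted over the list alone), FRZB among the latter at -1.70 (adjusted p = 0.00436). Of 12 measured neural genes 0 rose and 8 fell (11 adjusted over the list alone): MAP2 (-2.005, adjusted p = 0.00121), SIX3 (-1.84, adjusted p = 0.00328, and 0.0534 without untreated library 2) and SOX3 (-1.56, adjusted p = 0.00212). Neuroectoderm-like cells made up 19.0% ± 2.9 of the cells at 20 h and 39.1% ± 10.7 untreated, and without them 5 of 6 neural genes still fell and 471 genes changed. Of 27 pluripotency genes 1 rose (GDF3, 3.68) and 7 fell (16 adjusted over the list alone), OTX2 by 1.43 and FGF2 by 1.19. Of 8 fibroblast genes 1 rose and 3 fell (6 adjusted over the list alone), with TAGLN, an actin-binding protein, falling from 309 ± 56.5 to 48.9 ± 5.96 CPM (log2 -2.66, SE 0.165, adjusted p = 1.63e-09). Of 4 trophoblast genes 2 rose and 1 fell (3 adjusted over the list alone), TFAP2C among those that rose (1.59).

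Of 22 glycolysis genes 4 rose, PDK1 by 2.76 and BNIP3 by 0.91 (5 adjusted over the list alone). Of 12 genes of the epithelial to mesenchymal transition 1 rose and 3 fell, VIM by 1.14. Of 27 cell cycle genes 3 rose, MCM2 by 1.12, and 3 fell, CDKN1A by 2.28. None of the 13 DNA methylation genes passed in edgeR (0, and 0 adjusted over the list alone, the lowest counts of any list). Among the other large rises was MT1G, a metallothionein (3.32), and among the other large falls were JAKMIP2-AS1 (-3.34), ABHD12B (-3.31), SORBS2 (-2.98), LIMCH1 (-2.82), IRX2 (-2.37), CYR61 (-2.14), SNORA25 (-2.12) and AJUBA (-2.10). Camera held with an estimated correlation for amnion (adjusted p = 0.00359), BMP (0.00359), WNT (0.0123), streak (0.0172) and neural ectoderm (0.0343). The calls with the preset correlation of pluripotency (adjusted p = 0.00257), trophoblast (0.00922) and fibroblast genes (0.000334) were lost, each at adjusted p = 0.0755 with an estimated correlation, and that of glycolysis (0.00774) at adjusted p = 0.192 with an estimated correlation. The median and the test of the germ cell list differed in sign (0.18, test down), as did the median and mean of later mesoderm (-0.13 and 0.48) and of cell cycle genes (0.039 and -0.007). Time, culture in 3D and plate changed together here. Of 35 splits of the libraries the real one was highest, with 104 as the next. The count fell to 298 without untreated library 3 and to 346 without untreated library 2. Without untreated library 2 adjusted p was 0.0584 for FRZB, 0.0543 for TFAP2C and 0.0808 for MCM2, without untreated library 3 it was 0.0653 for TFAP2C and 0.111 for BNIP3, and without untreated library 4 it was 0.107 for MCM2.

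The comparison of 48 h with 20 h of BMP4 asks which lineages appear on the second day, where time and plate changed together. Genes of mesoderm, endoderm and amnion rose, and pluripotency genes fell. Of 11582 genes tested (4 libraries against 4), 2319 changed, 1110 up and 1209 down. Of 22 measured streak genes 17 rose and 1 fell (20 adjusted over the list alone). WNT5A, a non-canonical WNT ligand, rose from 0.584 ± 0.434 to 63.9 ± 15 CPM (SD, n = 4 each; log2 6.58, SE 0.377, edgeR adjusted p = 2.5e-09). LHX1, a factor of the anterior streak, rose by 5.41 (SE 0.452, adjusted p = 2.64e-07), FGF17 by 5.05 (adjusted p = 3.79e-06), and TBX6, a factor of paraxial mesoderm, by 4.94 (adjusted p = 2.88e-08). Of 14 later mesoderm genes 12 rose and 0 fell (13 adjusted over the list alone). GATA6 had 3 counts at 20 h and rose 51.3-fold (counting interval 17.3 to 251), GATA4 rose by 4.41 (adjusted p = 6.25e-06), and HAND1, a factor of lateral mesoderm and amnion, from 7.97 ± 6.34 to 169 ± 69.2 CPM (log2 4.32, adjusted p = 3.94e-07). Of 12 endoderm genes 8 rose and 0 fell (8 adjusted over the list alone), with SOX17, a factor of endoderm and germ cells, at 4.32 (adjusted p = 4.95e-05).

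Of 18 amnion genes 13 rose and 1 fell (17 adjusted over the list alone). GABRP, a GABA receptor subunit, stood at 22.6 ± 16.4 CPM against 0 counts at 20 h (at least 56.4-fold), and EPAS1, a hypoxia-inducible factor, rose by 5.09 (adjusted p = 1.3e-07). Of 11 germ cell genes 4 rose and 4 fell (8 adjusted over the list alone), NANOS3, a regulator of germ cell survival, rising by 3.94 (adjusted p = 0.000103) and UTF1 falling by 3.49. Of 26 pluripotency genes 4 rose and 18 fell (24 adjusted over the list alone), UTF1 from 10.3 ± 2.15 to 0.923 ± 0.41 CPM (adjusted p = 1.29e-05), PRDM14 by 2.83 (adjusted p = 3.45e-05) and POLR3G by 1.59 (adjusted p = 6.55e-05). Of 18 WNT targets 13 rose and 1 fell (15 adjusted over the list alone). DKK4 had 1 count at 20 h and rose 193-fold (counting interval 34.2 to 7649), DKK1 rose by 3.08, and BMP4 by 3.43 (adjusted p = 9.35e-06; 170 ± 124 against 16.1 ± 7.33 CPM). Of 20 BMP targets 8 rose and 3 fell (14 adjusted over the list alone), BMPER at 4.12 among those that rose. The other large rises were BMP2 (5.24, adjusted p = 2.84e-08) and CYP26A1, which degrades retinoic acid, with 3 counts at 20 h (55.8-fold, 18.8 to 273).

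Of 14 genes of the epithelial to mesenchymal transition 7 rose and 1 fell (10 adjusted over the list alone), SNAI1 by 3.93 and FN1, fibronectin, by 2.09 (adjusted p = 1.09e-07). Of 13 neural genes 7 rose and 0 fell (7 adjusted over the list alone), PAX6 by 1.76, CDH2 by 1.73 and LHX2 by 1.71. Neuroectoderm-like cells made up 32.2% ± 7.8 at 48 h and 19.0% ± 2.9 at 20 h, and without them 2 of 6 neural genes rose and 1 fell. CDH2 rose by 2.56 in the other cells and by 0.12 in Neuroectoderm-like cells, where the other cells were of different types at the 2 times. Of 24 glycolysis genes 13 rose and 1 fell (14 adjusted over the list alone), P4HA1 by 2.27 and BNIP3 by 2.23 (adjusted p = 2.99e-08), with ADM falling by 1.84. Of 27 cell cycle genes 3 rose and 8 fell (12 adjusted over the list alone), CCND1 by 1.03. Of 15 DNA methylation genes 3 rose (GADD45A, 1.38, TET2, 1.11, and UHRF2, 0.94) and 1 fell (4 adjusted over the list alone). Of 5 trophoblast genes 2 rose (TFAP2C, 0.99, and TEAD3, 0.83), of 5 naive pluripotency genes 1 rose (TBX3, 3.023), of 9 fibroblast genes 6 rose (COL5A1, 2.16) and 2 fell (THY1, -1.35), and of 15 stress genes 3 rose (DDIT4, 2.34) and 2 fell. LMO2, of the blood and endothelium list, rose by 1.13 (adjusted p = 0.0292), but did not pass without 48 h library 3 (0.78, adjusted p = 0.15), 20 h library 1 (adjusted p = 0.0877) or 20 h library 3 (adjusted p = 0.0675). PAX6 did not pass without 48 h library 2 (adjusted p = 0.0611), 20 h library 1 (0.0662) or 20 h library 3 (0.0635). TET2 did not pass without 48 h libraries 2, 3 or 4 (adjusted p = 0.062, 0.099 and 0.105) or 20 h libraries 1, 2 or 3 (adjusted p = 0.0846, 0.0774 and 0.145). Among genes that reached 20 CPM the largest falls were of 7 near-identical SNAR-A genes (SNAR-A11, A3, A5, A10, A6, A14 and A9), from -3.85 to -3.14, followed by CAMKV (-3.04), LOC100131138 (-2.86) and CBLN1 (-2.75).

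Camera held with an estimated correlation for later mesoderm (adjusted p = 0.00222), streak, endoderm and WNT (0.00271 each), amnion, epithelial to mesenchymal transition and pluripotency (0.0029 each), glycolysis (0.016) and BMP (0.027). The preset calls of neural ectoderm (adjusted p = 0.000159) and trophoblast (0.036) were lost, at adjusted p = 0.116 and adjusted p = 0.102 with an estimated correlation. Among lists that did not pass, germ cell (median -0.22, mean 0.38, test down), DNA methylation (-0.15 and 0.05), naive (-0.14 and 0.42) and stress genes (-0.07 and 0.05) had a median and a mean of different sign. Thinning every cell to 5000 UMIs left 395 changed genes. Of the 35 splits of the libraries the real one was highest, with 0 as the next.

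**Figure D1:**
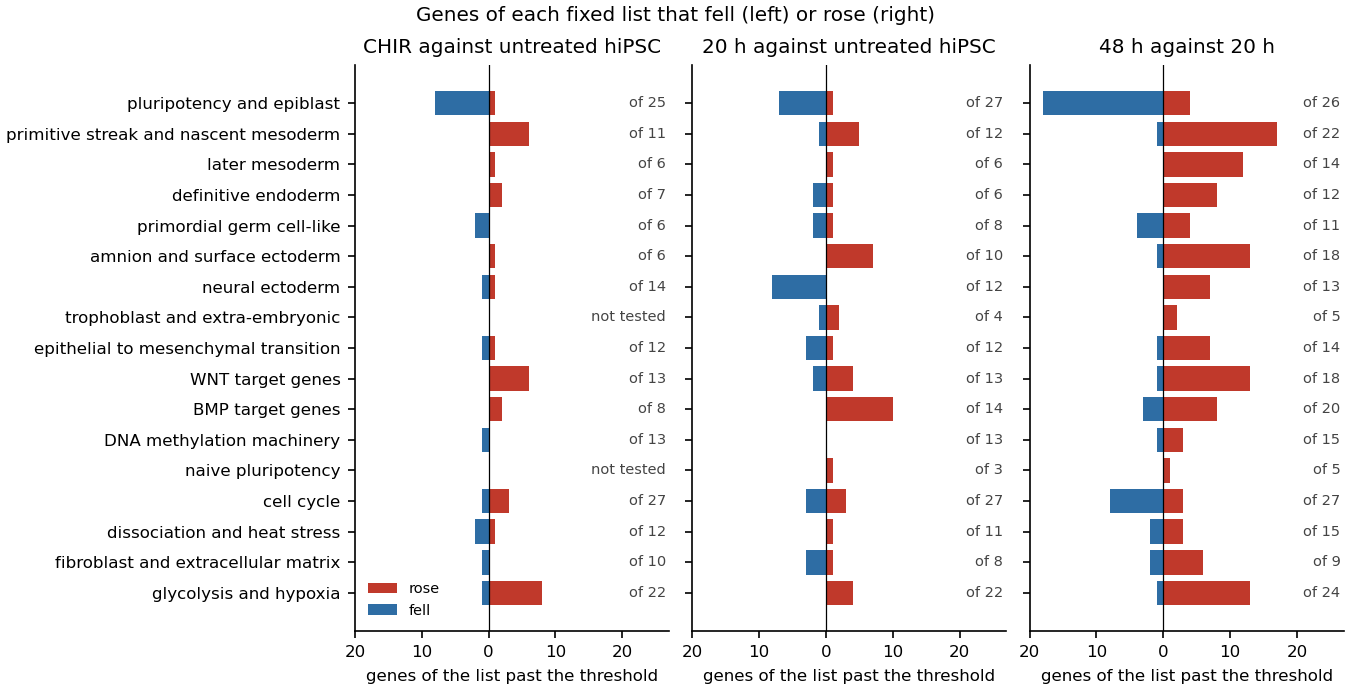
Number of genes of each fixed list that fell (bars to the left) or rose (bars to the right) past the threshold in 3 comparisons, with the number measured at the right of each panel. With CHIR99021 8 glycolysis and 6 streak genes rose and 8 pluripotency genes fell, at 20 h 10 BMP targets rose and 8 neural genes fell, and at 48 h 18 pluripotency genes fell.

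The 36 h libraries were read by scRNA-seq, so time, plate and assay changed together in the comparisons with 20 h and with 48 h. At 36 h against 20 h (3 libraries against 4), 7195 of 12613 genes changed, 3780 up and 3415 down, and the next highest of 35 splits gave 4511. Lineage genes rose here as well: WNT5A (log2 6.49, adjusted p = 9.21e-11), LHX1 (5.23), EPAS1 (5.05), SNAI1 (4.43) and HAND1 (3.93), with GABRP at least 57.2-fold, GATA6 at 99.5-fold (3 counts at 20 h, counting interval 33.8 to 484), CYP26A1 at 99-fold (3 counts, 33.6 to 482) and CER1, a nodal and BMP antagonist, at 49.1-fold (3 counts, 16.6 to 240). GMPR had 1 count at 20 h and rose 223-fold (39.6 to 8819), and HPGD rose by 4.90. Streak genes rose in 17 of 25 (1 fell), later mesoderm in 17 of 19, endoderm in 14 of 16, amnion in 17 of 21, neural ectoderm in 10 of 15, BMP targets in 14 of 20 and WNT targets in 13 of 21 (1 fell). Pluripotency genes rose in 7 of 26 and fell in 13, UTF1 (-3.203) and PRDM14 (-1.96) among the latter, while ZIC2 rose by 2.02. Camera held with an estimated correlation for later mesoderm (adjusted p = 0.0163), streak (0.0434), endoderm, WNT, BMP and epithelial to mesenchymal transition (0.0359 each). The calls of amnion, neural ectoderm and glycolysis were lost, at adjusted p = 0.102, adjusted p = 0.182 and adjusted p = 0.117 with an estimated correlation. Germ cell (0.09, test down), DNA methylation (-0.17 and 0.34) and naive genes (-0.31 and 0.49) differed in the sign of their median and test or mean.

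Other genes rose as well. DDIT4, a stress-induced inhibitor of mTOR, rose from 5.33 ± 3.74 to 205 ± 48.5 CPM (log2 5.23, edgeR adjusted p = 3.23e-11), KDM1A, a histone demethylase, from 5.71 ± 0.813 to 75.3 ± 5.47 CPM (3.73, adjusted p = 2.37e-11), and UBE2C (2.94), PCNA (2.24), P4HA1 (3.68), CITED2 (3.37) and BNIP3 (2.96) rose as well. SNAR-A14 and SNAR-A11 had 0 counts at 36 h (at least 194-fold and 192-fold lower). At 48 h against 36 h, 5052 of 12613 genes changed, 2436 up and 2616 down, and the next highest of 35 splits gave 2511. TMSB4X, which binds actin monomers, fell from 940 ± 74.9 to 61.2 ± 36.3 CPM (-3.91, adjusted p = 5.59e-09), and MTA3 (-4.58), RAB12 (-4.35), GMPR (-4.30), RNPEP (-3.87), NCSTN (-3.83), KDM1A (-3.80), PSMB3 (-3.72), ACAT1 (-3.72), UBE2C (-3.56), MYC (-3.43), DDIT4 (-2.87) and CDC20 (-2.82) fell with it. SNORA25 (4.75), BCYRN1 (3.16), CNTFR (2.68), LEFTY2, a nodal inhibitor (2.59), HIST1H2AJ (2.21), PLA2G2A (2.13), MINK1 (1.81), ITGA5 (1.39) and TBX6 (1.34) rose. Cell cycle was the only list that camera called at 48 h against 36 h (3 of 27 rose and 9 fell, adjusted p = 0.0309), and the call was lost at adjusted p = 0.569 with an estimated correlation. Germ cell (median 0.16, test down), trophoblast (0.14, test down), amnion (0.02 and -0.09), naive (0.009 and -0.067) and fibroblast genes (-0.07 and 0.06) differed in the sign of their median and test or mean.

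**Figure D2:**
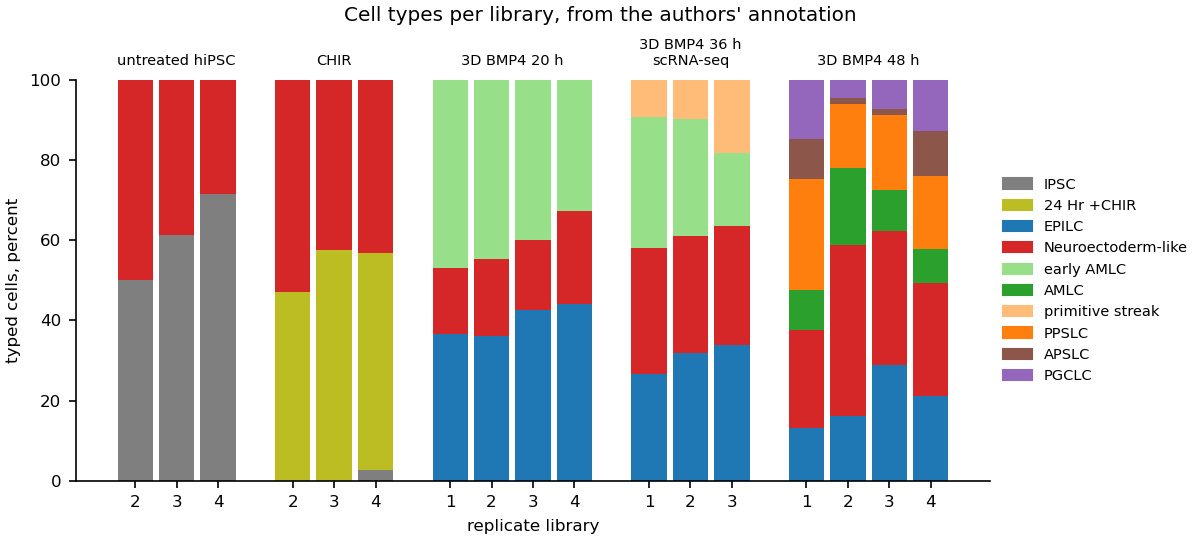
Share of typed cells (percent, vertical axis) of each of the authors' cell types, stacked in a bar for each replicate library (horizontal axis) of the untreated, CHIR99021 and BMP4 arms. Neuroectoderm-like cells average 39.1% untreated, 46.2% with CHIR99021, and 19.0%, 30.1% and 32.2% at 20, 36 and 48 h.

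The authors' cell types, named from RNA, ask which cells the colonies contain at each time. At 20 h the typed cells were early amnion-like (41.1% ± 6.3, SD, n = 4), epiblast-like (39.9% ± 4.1) and Neuroectoderm-like (19.0% ± 2.9). At 36 h primitive streak cells made up 12.4% ± 5 (n = 3). At 48 h posterior primitive streak-like cells made up 20.3% ± 5.2, epiblast-like cells 19.9% ± 6.9, amnion-like cells 11.9% ± 4.9, primordial germ cell-like cells 9.8% ± 4.8 and anterior primitive streak-like cells 6.0% ± 5.3 (n = 4). As the types were called on RNA, genes that mark a type are not results. Lists of other functions are given here as description, since they come from the same RNA and are not independent of the types either. The same holds for DNMT3B, a member of the fixed pluripotency list, and for the counts of changed genes by type below. At 48 h amnion-like cells against the other types had 11 of 24 cell cycle genes lower and 2 higher, CCND1 at -1.84, TYMS at -1.85 and RRM2 at -1.33, with the inhibitor CDKN1C at 1.86. They had 10 of 22 glycolysis genes lower and 2 higher, BNIP3 at -1.63. Epiblast-like cells had glycolysis genes higher in 16 of 20 at 20 h (1 lower), 22 of 24 at 36 h and 10 of 22 at 48 h, and anterior streak-like cells in 9 of 22. HK2, a hexokinase, stood at 1.62 and LDHA, lactate dehydrogenase, at 0.82 in epiblast-like cells at 20 h, and PDK1 at 1.53 at 48 h.

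Neuroectoderm-like cells had stress genes lower in 6 of 9 at 20 h, 9 of 16 at 36 h, 7 of 11 at 48 h and 6 of 9 with CHIR99021, with 0 higher in these, and EGR1 at -2.96 at 48 h. In untreated hiPSC 0 of 9 were lower and 1 was higher. DNMT3B was lower in Neuroectoderm-like cells by 1.92 at 20 h, 1.22 at 36 h, 1.52 at 48 h, 2.00 in untreated hiPSC and 1.75 with CHIR99021, and higher in epiblast-like cells by 1.26 at 20 h, 1.03 at 36 h and 1.26 at 48 h. The counts of changed genes at 48 h, out of 8840, were 2273 for Neuroectoderm-like, 1430 for posterior streak-like, 1365 for amnion-like, 574 for epiblast-like, 341 for anterior streak-like (2 libraries) and 336 for germ cell-like cells (3 libraries). Without library 2 those of Neuroectoderm-like, posterior streak-like, amnion-like and epiblast-like cells were 1450, 809, 776 and 382, and without library 3 those of Neuroectoderm-like, posterior streak-like and epiblast-like cells were 1369, 835 and 359. Without library 1 germ cell-like cells gave 206 and anterior streak-like cells 175, and the latter gave 214 without library 4. Anterior streak-like cells were then in 1 library, which was assumed to vary like the other types.

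At 36 h, out of 10548 genes, 3235 changed in Neuroectoderm-like, 1475 in epiblast-like, 1325 in early amnion-like and 1418 in streak cells. Without library 1 the first 3 gave 2056, 953 and 859, and without library 3 the streak cells gave 730. At 20 h, out of 8485, the counts were 2697 for Neuroectoderm-like, 1249 for epiblast-like and 1920 for early amnion-like cells, the last falling to 1170 without library 4. Neuroectoderm-like cells differed from the other cells in 959 of 7513 genes untreated and 1773 of 7937 with CHIR99021. The change with CHIR99021 differed between Neuroectoderm-like and other cells in 73 of 8778 genes, and that from 20 to 48 h in 196 of 10528. The types were called on the same RNA in each arm and at each time. With the arms or times of the libraries exchanged, at most 0 genes passed for CHIR99021 (4 arrangements, too few for a share under 0.05) and at most 31 for the times (35 arrangements).

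GpC calls in 10 kb bins ask where chromatin opens or closes. With CHIR99021, 100 of 255178 bins changed in edgeR (44 in DESeq2), 4 up and 96 down. The largest rise was on chromosome 1 at 226410001 to 226420000 (hg19), from 4.41 ± 1.12 to 15.2 ± 3.0 CPM (SD, n = 3 each; log2 1.76, SE 0.215, edgeR adjusted p = 1.01e-09), and the other rises, on chromosomes 5 (16160001, 1.21), 2 (224840001, 1.02) and 14 (51360001, 1.00), did not pass without library 2 (adjusted p = 0.287, 0.071 and 0.0931) or library 3 (adjusted p = 0.518, 0.555 and 0.455), nor those on 5 and 14 without library 4 (adjusted p = 0.478 and 0.204). Of the 5 largest falls, those on chromosome 15 at 25260001 (-1.57, adjusted p = 6.99e-08) and 7 at 121710001 (-1.38, adjusted p = 3.69e-07) held without each library. Those on chromosome 15 at 77900001 (-1.63) and 8 at 41120001 (-1.56) did not pass without library 3 (adjusted p = 0.0743 each), and the former and that on chromosome 4 at 129790001 (-1.44) not without library 4 (adjusted p = 0.347 and 0.156). The count was 15 without library 4 and 28 without library 3, and 35 without Neuroectoderm-like cells, where thinning all cells to the same totals left 33. For 5mC in 100 kb bins, 0 of 26733 changed in edgeR with CHIR99021 (1623 below 0.05 unadjusted, 0 in DESeq2, and 2 in edgeR with the library as a block). Of the 4 splits that part as many pairs, the highest other gave 0 GpC bins and 7 5mC bins, too few splits for a share under 0.05.

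Between 20 h and 48 h, 8083 of 261482 GpC bins changed in edgeR (3.09%; 1094 in DESeq2), 2488 up and 5595 down, and 5927 of 26800 5mC bins (22.1%; 4984 in DESeq2), 2056 up and 3871 down. The median absolute log2 fold change of the latter was 0.347, and 4 reached 2-fold. The GpC bin on chromosome 17 at 39680001 to 39690000 rose from 7.40 ± 1.37 to 28.2 ± 2.61 CPM (SD, n = 4 each; log2 1.92, SE 0.191, edgeR adjusted p = 1.39e-13). Larger rises were on chromosomes 19 (24510001, 2.26), 16 (46400001, 2.11), 8 (47440001, 2.06) and 7 (58040001, 1.98), and the largest falls on chromosomes 16 (33230001, -2.61), 17 (62020001, -1.77), 1 (2490001, -1.74), 17 (2800001, -1.64) and 7 (1380001, -1.62). Those on chromosomes 1 and 7 (1380001) did not pass without 20 h library 1 (adjusted p = 0.0554 and 0.053), 17 (2800001) without 20 h library 2 (adjusted p = 0.0638) and 7 (58040001) without 48 h library 3 (adjusted p = 0.0709). The bins of these larger rises and of the falls had few calls, with means per library of 9.1 to 15.4. The median over all GpC bins was 29.9, and the bin on chromosome 17 at 39680001 had 165.6. The 5mC bin on chromosome 22 at 50300001 to 50400000 fell from 11.2 ± 0.832 to 5.34 ± 1.12 CPM (log2 -1.07, adjusted p = 0.000711). The other falls were on chromosomes 15 (102500001, -1.33), 22 (21700001, -0.93), 8 (144600001, -0.93) and 12 (132700001, -0.92), and the rises on chromosomes 11 (54700001, 1.24), 10 (17900001, 1.04), 21 (10000001, 0.98), 7 (61200001, 0.85) and 4 (59700001, 0.71). All these 5mC bins had fewer calls than most, with means per library of 12.5 to 94.5 against a median of 225.5 over all 5mC bins.

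Calls of these 5mC bins ended as well when 1 library was left out. That on chromosome 7 ended without 48 h libraries 2, 3 and 4 (adjusted p = 0.0714, 0.0741 and 0.219) and 20 h libraries 1 to 4 (0.155, 0.0808, 0.0577 and 0.0573). That on chromosome 10 ended without 48 h library 1 (adjusted p = 0.111) and 20 h libraries 1 and 2 (0.098 and 0.0838). Without 48 h library 3 those on 4 and 22 (21700001) ended (adjusted p = 0.0887 and 0.0677), and without 48 h library 4 that on 12 (0.0686). Without 20 h library 2 those on 4, 12, 21 and 22 (21700001) ended (adjusted p = 0.102, 0.0551, 0.0515 and 0.0606), and without 20 h library 3 that on 22 (0.0642).

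The median change differed between chromosomes, but with each autosome scaled to its own total 6165 GpC and 5520 5mC bins still changed. The median log2 fold change of chromosome 19 was -0.32 for GpC and -0.33 for 5mC, of chromosome 22 -0.31 and -0.28, and of chromosome 4 0.15 and 0.13. Over the 22 autosomes the GpC and 5mC medians correlated at r = 0.996 (rho 0.99, r 0.993 without the 2 farthest), and each with the GC content of the transcripts at r = -0.895 (rho -0.888, and -0.837 without the 2 farthest) and -0.894 (rho -0.893, and -0.837), with permutation p = 1e-05 each, the smallest possible. With CHIR99021 the GpC medians correlated with transcript GC at r = -0.657 (rho -0.552, permutation p = 0.00096, and r -0.425 without the 2 farthest). Autosomes are not independent replicates. Of 35 ways to part the libraries, the real one ranked below 1 in GpC bins (8759) and below 2 in 5mC bins (up to 8052). These put 48 h library 1 with 3 of the 20 h libraries. Calls in the bins with most over those with fewest stripped DNA calls stood at log2 0.278 (GpC) and 0.183 (5mC) in this library. The other 48 h libraries stood at 0.511 to 0.644 and 0.409 to 0.561. Those of 20 h stood at 0.101 to 0.36 and 0.091 to 0.255, so 48 h library 1 lay within the 20 h range in this trend. Without 48 h library 1 the counts were 23686 GpC and 13500 5mC bins. Without 48 h libraries 2, 3 and 4 they were 3152, 1563 and 2683 GpC and 3265, 2667 and 2536 5mC bins, and without 20 h libraries 1 and 2 they were 2290 and 2087 GpC and 2631 and 2465 5mC bins. Without Neuroectoderm-like cells 2291 GpC and 2905 5mC bins changed, and with all cells thinned to the same totals 3369 and 4455.

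**Figure D3:**
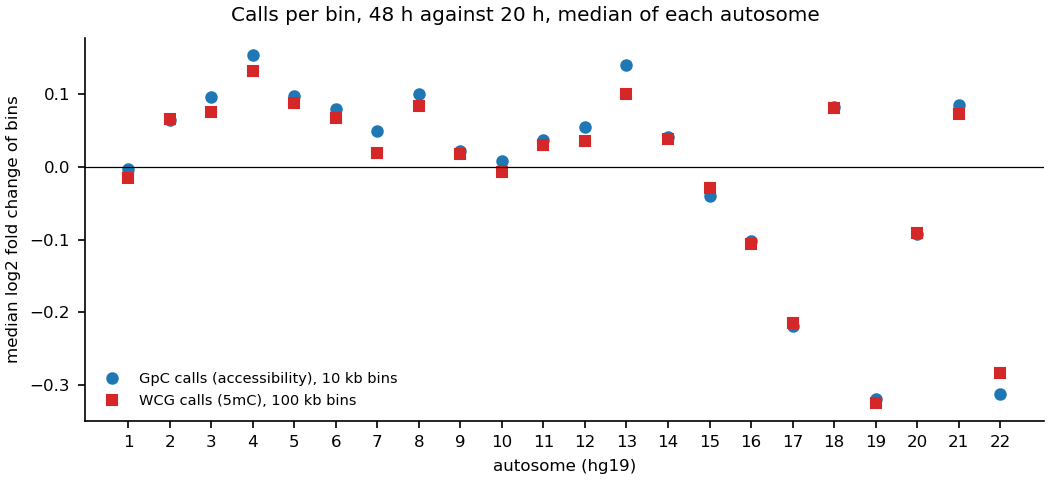
Median log2 fold change at 48 h against 20 h (vertical axis) of GpC calls in 10 kb bins (circles) and of 5mC calls in 100 kb bins (squares) for each autosome (horizontal axis). Chromosomes 19 (-0.32 and -0.33) and 22 (-0.31 and -0.28) are lowest, and chromosome 4 is at 0.15 and 0.13.

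Neuroectoderm-like cells differed from the other cells of the same libraries in 97 of 93505 GpC bins untreated (14 higher, 83 lower), 116 of 142022 with CHIR99021 (9 and 107), 28 of 125609 at 20 h (9 and 19) and 331 of 255006 at 48 h (20 and 311). The bin on chromosome 3 at 112130001 to 112140000 was lower in all 4 arms (-3.49, -3.62, -2.89 and -2.88 in that order). Those on chromosome 12 at 48360001 (2.11, 2.40, 2.80 and 2.44) and chromosome 14 at 101200001 (2.53, 1.86, 2.53 and 1.92) were higher in all 4. The bin on chromosome 1 at 226410001 that rose with CHIR99021 was lower in Neuroectoderm-like cells at 20 h (-2.04) and 48 h (-3.79). No 5mC bin of 100 kb differed in any of the 4 arms in edgeR (0 each, with 1883, 1777, 1714 and 1686 below 0.05 unadjusted). Bins were scaled to the total of calls, so a shift shared by all bins cannot show here. The smallest sum, at 20 h, held 505765 calls.

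Calls per cell bear on total methylation only indirectly. WCG calls also vary with depth, and the ratio of WCG to GpC calls also varies with GpC calls. In HEK293T this ratio was 0.241 by scMA-seq and 0.387 by scMAT-seq (1 library each). The ratio of WCG to GpC calls per cell, averaged by library, was 0.719 ± 0.034 at 48 h and 0.862 ± 0.083 at 20 h (SD, n = 4 each; exact two-sided permutation p = 0.0571) and 0.698 ± 0.058 untreated (n = 3; 20 h against it exact p = 0.0571). With CHIR99021 it was 0.662 ± 0.019 (n = 3; exact p = 0.5 against untreated). Log2 WCG calls per cell differed by -0.18 with CHIR99021 (exact p = 0.6), 0.14 at 48 h against 20 h (exact p = 0.314) and -0.18 at 20 h against untreated (exact p = 0.457). Without 20 h library 2 these were 0.27 (exact p = 0.0286) and -0.31 (exact p = 0.1), and the last was 0.0144 without untreated library 4 and -0.3144 without untreated library 3. With CHIR99021 it was -0.0855 without library 4, and at 48 h 0.0908 without 20 h library 1. The test with CHIR99021 did not pair the arms of a library, and log2 WCG calls were lower in treated cells in each. They were 16.45 against 16.55 untreated in library 2, 16.33 against 16.40 in library 3 and 16.70 against 17.06 in library 4. The smallest p of 3 libraries against 3 is 0.1, and of 4 against 4 or 3 it is 0.0286. The imbalance of 5mC between strands within a cell, as excess variance over autosomes times 1000, was 0.242 ± 0.237 with CHIR99021 and 0.0561 ± 0.0122 untreated (exact p = 0.1; the difference of 0.1857 was 0.0528 without library 3, and the medians over cells were 0.0495 and 0.0441), and 0.0922 at 48 h against 0.0562 at 20 h (exact p = 0.0571).

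The authors' sheets also count calls at WCpA, methylation outside CpG. In H9 the ratio of WCpA to WCpG calls was 0.604 by scMspJI-seq (1 library) and 0.315 to 0.360 by scMAT-seq. Assay, plate and depth differed there, so the ratio varies within a line for reasons that were not tested. Plate changed with time in the BMP4 libraries as well. The ratio of WCpA to WCpG calls fell from 0.322 ± 0.016 at 20 h to 0.240 ± 0.043 at 48 h (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible), and was 0.263 ± 0.018 in untreated hiPSC (n = 3; 20 h against it exact p = 0.0286) and 0.239 with CHIR99021 (exact p = 0.3). Neuroectoderm-like cells stood at 0.143 ± 0.026 and the other cells at 0.327 ± 0.045, lower in 11 of 11 libraries (exact two-sided sign-flip p = 0.000977, the smallest possible). By arm the values were 0.134 against 0.368 at 20 h, 0.154 against 0.283 at 48 h, 0.157 against 0.309 with CHIR99021 and 0.124 against 0.351 untreated. Without these cells the difference of 20 h from untreated hiPSC was 0.0122 (exact p = 0.314). Over all cells the difference of 48 h from 20 h no longer passed 0.05 when any 1 of the 20 h libraries was left out. The libraries still did not overlap, with at most 0.280 at 48 h and at least 0.305 at 20 h. The loss therefore reflects the few arrangements of so few libraries. At 48 h epiblast-like cells stood at 0.327, anterior streak-like at 0.338, posterior streak-like at 0.272, germ cell-like at 0.272 and amnion-like cells at 0.224. Amnion-like cells were below epiblast-like cells by 0.103 in 4 of 4 libraries (exact p = 0.125, the smallest possible). Their WCG calls per GpC call were higher by 0.139 in 4 of 4 libraries (exact sign-flip p = 0.125). WCpA calls per GpC call differed by -0.0301, with 1 of 4 libraries the other way (exact sign-flip p = 0.25). Fewer WCpA calls in amnion-like cells were therefore not established. WCG calls per GpC call were higher in Neuroectoderm-like cells, at 0.859 against 0.730 in 11 of 11 libraries.

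**Figure D4:**
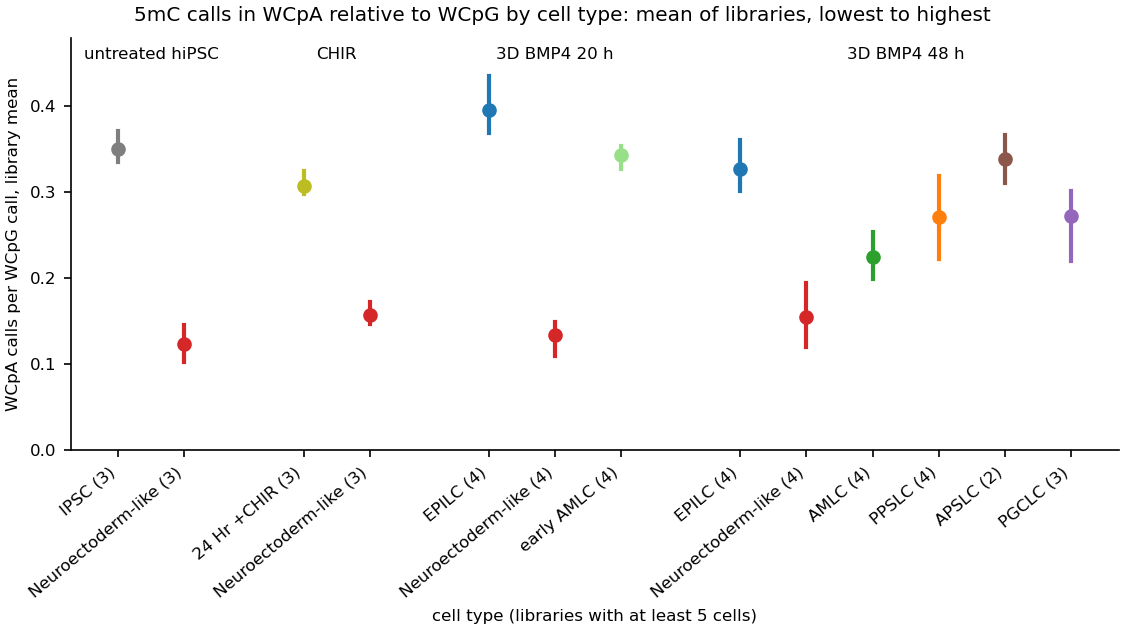
WCpA calls per WCpG call (vertical axis) by cell type and arm (horizontal axis); points are means over libraries with at least 5 cells of the type, their number in brackets, and lines run from the lowest to the highest library. Neuroectoderm-like cells are lowest in each arm, from 0.124 untreated to 0.157 with CHIR99021.

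The H9 libraries ask whether freezing changes the layers. By their titles the fresh and the frozen libraries were on different plates, so freezing and plate changed together. Median UMIs per cell were 19022 and 13242 in the fresh and 24619 and 26602 in the frozen libraries. In frozen against fresh cells (2 libraries each) 4 of 8574 genes passed in edgeR, all lower: GPR82 (-1.56), LMOD3 (-2.62), LRAT (-1.56) and SHROOM1 (-1.10). Over 96.0% of each row's total came from values split with other rows, so these calls are uncertain. None passed in DESeq2 (0), 486 genes were below 0.05 unadjusted, and the count was 43 and 46 without fresh libraries 3 and 4 and 2 without frozen library 2, where the lone library was assumed to vary like the other group. In no list did a member pass (0 of each in edgeR), and the lowest camera p was that of DNA methylation (adjusted p = 0.475). Germ cell (median -0.05, test up), amnion (0.18 and -0.01) and epithelial to mesenchymal transition genes (-0.05, test up) differed in the sign of their median and test or mean. L1TD1 stood at 1224 ± 94.5 frozen and 1430 ± 47.1 CPM fresh, POU5F1 at 739 ± 55.1 and 568 ± 89.4 CPM, and CCND1 at 55.5 ± 5.93 and 75.3 ± 5.98 CPM. In simulated data of this depth, 27% of 2-fold and 82% of 4-fold changes were found. The WCG to GpC ratio was 0.684 frozen and 0.533 fresh (exact p = 0.333, the smallest possible).

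HEK293T had 1 scMAT-seq library and was set beside the 4 of H9 without a test. FOXC1 stood at 267 CPM and at 0.28 in H9 (1 count; 704-fold by summed counts, as are the other folds with counts here, counting interval 124 to 2.8e+04), MSX1 at 79.4 CPM (1 count in H9; 209-fold, from 35.3), and CDKN2A, a cell cycle inhibitor, at 489 CPM with 0 counts in H9 (at least 429-fold). SNAR-A7, A14, A4, A11 and A6 were higher as well. Lower in HEK293T were APOE (1 count in HEK293T; 527-fold, from 94.5), SFRP2 (1 count; 251-fold, from 44.9), SFRP1, a WNT antagonist, with 0 counts in HEK293T (at least 168-fold), EPCAM (1 count; 143-fold, from 25.6), CLU (1 count; 146-fold, from 26.2), DNMT3B at 8.36 against 720 CPM (81-fold, 31.6 to 298), POLR3G (1 count; 77.8-fold, from 13.9) and SPARC (1 count; 74.2-fold, from 13.2). All 21 measured pluripotency genes were below all 4 H9 libraries (median log2 -4.07). Medians were -2.86 for endoderm, -2.35 for germ cell and -2.22 for fibroblast genes. The share of GpC calls on chromosomes 13 and 21 was 0.43 and 0.44 log2 units higher in HEK293T than in H9, and that on chromosomes 17 and 19 lower by 0.44 and 0.35. Over the 22 autosomes these shares correlated between scMA-seq and scMAT-seq at r = 0.965 (rho 0.932, r 0.941 without the 2 farthest, permutation p = 1e-04 each), and with transcripts at r = 0.137 (permutation p = 0.55).

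In the H9 test of beads, messenger RNA of the same 38 cells was read after each of 5 enrichments. The median was 16442 UMIs per cell with C1 beads (95% interval 14012 to 19829), 18534 with M270, 14753 with C1 and the RNA left on the bead, 8134 with M280 and 6478 with T1, and genes per cell were 5123, 5530, 4674, 3300 and 2799. M270 exceeded C1 in 38 of 38 cells, with a median ratio of 1.118. At an equal 2319 UMIs the genes per cell were 1430, 1437, 1398, 1388 and 1384. Across 8012 genes the enrichments correlated at 0.88 to 0.971, where genes are not independent replicates. Empty wells of all libraries held a median of 65.8 UMIs, 1042 WCG calls and 1249.5 GpC calls, which are 0.23%, 1.25% and 0.94% of kept cells.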

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

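The tests of the WCpA ratio, of the 36 h transcripts and of GC content along autosomes, and the exchanges of libraries for expression, bins and 5mC, were chosen after the results were seen, as were the counts of bins kept, while the bounds for density and cell share and the tests of interactions and cell kinds were set before.

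Neuroectoderm-like cells had fewer WCpA calls per WCpG call than the other cells. At equal log2 WCG calls the ratio was still lower, by -0.1814, which argues against depth. WCpA calls per GpC call were lower in 11 of 11 libraries (0.118 against 0.235), which argues against more WCpG calls as the whole cause. Lower DNMT3B transcript stays open: within a type and library the ratio followed DNMT3B at a mean rank correlation of 0.168 (exact two-sided p = 0.0166, adjusted p = 0.0469, above 0 in 9 of 11 libraries), but GAPDH gave 0.14 (adjusted p = 0.0469), so the 2 cannot be told apart. DNMT3A gave -0.071, DNMT1 -0.04 and ACTB 0.031, none of which passed, and log2 WCG calls gave -0.307 (adjusted p = 0.00586, below 0 in 11 of 11 libraries).

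Many transcripts were high at 36 h by scRNA-seq and low in the scMAT-seq libraries on each side. Over 5279 of 5623 genes (93.9%) with a known 3' end, this ratio followed the longest run of T in the last 200 bases at equal GC content (rank correlation 0.151) and GC content at equal T run (-0.425). The same values were -0.044 and -0.24 for 48 h over 20 h, within one assay. A transient of the culture stays open, since time and assay changed together: of 12 genes 8-fold above both times, 8 (66.7%) were 4-fold above every other scMAT-seq group as well, and none (0) was 8-fold below both. A bias of one assay with the sequence of the 3' end may therefore account for part of the ratio.

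Many GpC and 5mC bins differed between 48 h and 20 h. Fitting each library's trend with calls in stripped DNA left 53.6% as many GpC bins (4335) and 81.9% as many 5mC bins (4855). The 5mC count met the bound set beforehand against the trend, but the same bins with the same sign, a measure taken up after, were 42.4% (3427) and 59.5% (3529), which meet none, and changes followed stripped calls at rank correlations of 0.291 and 0.363, so the part of the trend stays open. Without Neuroectoderm-like cells 49% as many 5mC bins passed (2905, of which 2818 were among the first 5927). This was under the bound of 50% set beforehand for these cells as the cause. Thinning alone to the same totals left 4455 (4095 among the first), so depth alone argues for part of the loss. Between these cells and the others 0 of 26656 5mC bins differed at 20 h and 0 of 26744 at 48 h in edgeR, in smaller sums. Whether these cells account for a further part therefore stays open. The medians of the autosomes followed transcript GC content at -0.895, so a bias with GC content may be at work, but with each autosome scaled to its own total 6165 GpC and 5520 5mC bins still changed, which argues against differences between autosomes as the whole cause.

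For expression, exchanging libraries gave 1 of 35 splits as large as the real one, the smallest share possible. This argues against chance but does not exclude it, as 42 tests of explanations and splits were made. It says nothing against an effect of plate. The counts were 2319 for 48 h against 20 h (highest other 0) and 7195 for 36 h against 20 h (4511). They were 5052 for 48 h against 36 h (2511) and 567 for 20 h against untreated cells (104). For bins at 48 h against 20 h, 2 of 35 splits gave as many GpC bins (8083; highest other 8759) and 3 as many 5mC bins (5927; highest other 8052), so chance cannot be excluded, and the larger splits put 48 h library 1 with 3 of the 20 h libraries. For CHIR99021 the 10 splits are too few for a share under 0.05: 1 was as large for genes (448; highest other 0), 1 for GpC bins (100; 1) and 10 for 5mC bins (0 in edgeR, 1623 unadjusted, 0 in DESeq2; 7). Exchanging Neuroectoderm-like and other cells gave too few splits as well: GpC bins 1 of 4 untreated (97; 0), 1 of 4 with CHIR99021 (116; 0), 1 of 8 at 20 h (28; 2) and 1 of 8 at 48 h (331; 11). For 5mC bins, at 0 in edgeR, they were 4 of 4 (highest other 1), 4 of 4 (0), 8 of 8 (0) and 8 of 8 (0), with 1883, 1777, 1714 and 1686 unadjusted.

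Exchanges of cell types within libraries (21 splits each) say nothing on chance, since the types were called on the same RNA. As large as the real one was 1 split for Neuroectoderm-like cells at 20 h (2697; highest other 1249), 36 h (3235; 329) and 48 h (2273; 34), early amnion-like cells at 36 h (1325; 243), and amnion-like (1365; 4), epiblast-like (574; 0), germ cell-like (336; 17) and posterior streak-like cells (1430; 79) at 48 h. As large were 2 splits for epiblast-like (1249; 2334) and early amnion-like cells (1920; 2320) at 20 h, and epiblast-like (1475; 1613) and streak cells (1418; 2371) at 36 h, each with Neuroectoderm-like cells in the place of the type in all libraries.

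The change differed between Neuroectoderm-like and other cells, by an interaction term, in 73 of 8778 genes with CHIR99021. In the exchanges 1 of 4 splits was as large, too few for a share under 0.05 (highest other 0). From 20 h to 48 h it differed in 196 of 10528 genes, with 1 of 35 splits as large (highest other 31). This argues against chance in the grouping of libraries but does not exclude it. The cells were typed on the same RNA in each arm and at each time, an effect that the exchanges do not test. In the CHIR99021 libraries the other cells were typed IPSC when untreated and, but for 1 cell, 24 Hr +CHIR when treated. With CHIR99021 the differences were -4.014 for SP5 (edgeR adjusted p = 9.04e-11; 1.27 in Neuroectoderm-like and 5.29 in other cells), -2.334 for FST (9.83e-10; 0.17 and 2.49), -3.945 for IER3 (4.75e-08; -2.19 and 1.79), -1.553 for KRT8 (3.29e-06; -1.06 and 0.50), -2.162 for ITGA5 (2.65e-05; -0.95 and 1.22) and -1.204 for KRT18 (0.000479; -1.23 and 0.02). From 20 h to 48 h they were 2.093 for SOX2 (8.55e-12; 0.19 and -1.94), -3.155 for MSX1 (2.54e-11; -0.58 and 2.52), -3.865 for APLNR (2.78e-10; 1.70 and 5.50), -2.337 for ITGA5 (4.37e-09; -0.30 and 2.06), -3.187 for LIX1 (9.87e-06; -0.22 and 2.92) and -2.486 for CDH2 (1.74e-05; 0.12 and 2.56).

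In 2 of 33 groups of 4 libraries 1 value lay far from the others, and chance alone gives about 1 in 20. Log2 WCG calls per cell were 16.8834 in 20 h library 2. Amnion-like cells were 19.1176% of typed cells in 48 h library 2.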

How the results depend on the processing

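Of 464 alternative values of 75 results that answer a comparison, 368 stayed the same, 12 were weaker, 6 stronger, 62 moved and 16 reversed. Of 2894 for 221 single genes, bins and counts by direction, 2702 stayed the same, 120 were weaker, 2 stronger and 70 moved, and 0 reversed. Where a value changed, the cause was not tested. The alternatives that drop Neuroectoderm-like cells, fit the trend with stripped DNA or scale autosomes were added after the data were seen.

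DESeq2 gave 238 genes with CHIR99021 (448 in edgeR), 0 in H9 (4), 44 GpC bins with CHIR99021 (100) and 1094 at 48 h against 20 h (8083). Thinning to 5000 UMIs left 63 genes with CHIR99021 and 395 at 48 h against 20 h (2319). The library as a block gave 832 genes with CHIR99021 (702 without Neuroectoderm-like cells), 2 5mC bins with CHIR99021 (0), 12674 GpC bins and 9234 5mC bins at 48 h (5927). Without a count filter 923 genes passed at 20 h against untreated (567) and 0 in H9. An estimated correlation called 5 lists at 20 h against untreated and 0 at 48 h against 36 h. Bins of 500 kb gave 1 with CHIR99021 and 2225 at 48 h.

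Without Neuroectoderm-like cells 35 GpC bins passed with CHIR99021, and 2291 GpC and 2905 5mC bins at 48 h. The WCG to GpC ratio then differed by -0.119 at 48 h against 20 h and by 0.1552 at 20 h against untreated (exact p = 0.0286 each), and the WCpA ratio by 0.0122 at 20 h against untreated (exact p = 0.314). Fitting the trend left 4335 GpC bins. The median over cells gave -0.0103 for log2 WCG calls at 48 h against 20 h (reversed, exact p = 0.971) and 0.1351 for the WCG to GpC ratio at 20 h against untreated (exact p = 0.0286). Mean absolute deviation after thinning gave 0.00175 for strands at 48 h (exact p = 0.0286). The combined annotation gave -0.0029 for strands of Neuroectoderm-like minus posterior streak-like cells (reversed, exact p = 0.75). With each cell thinned, genes per cell over C1 beads were 0.978 on the bead, 1.005 for M270, 0.97 for M280 and 0.968 for T1.

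With 1 library left out, counts ran from 150 to 324 genes with CHIR99021, 298 to 812 at 20 h against untreated, 2 to 46 in H9, 15 to 80 GpC and 0 to 1 5mC bins with CHIR99021 (edgeR), and 1563 to 23686 GpC and 2465 to 13500 5mC bins at 48 h. By type they ran from 1170 to 1635 (early amnion-like, 20 h); 859 to 1029 (early amnion-like), 953 to 1075 (epiblast-like), 2056 to 2607 (Neuroectoderm-like) and 730 to 992 (streak) at 36 h. At 48 h they ran from 776 to 1218 (amnion-like), 175 to 344 (anterior streak-like), 359 to 479 (epiblast-like), 1369 to 2285 (Neuroectoderm-like), 206 to 300 (germ cell-like) and 809 to 1142 (posterior streak-like).

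Log2 WCG calls ran from 0.0908 to 0.2733 at 48 h against 20 h (the latter without 20 h library 2, exact p = 0.0286) and from -0.3144 to 0.0144 at 20 h against untreated (reversed without untreated library 4). The WCG to GpC ratio ran from -0.1754 (without 20 h library 3, exact p = 0.0286) to -0.1102 at 48 h. The WCpA ratio ran from -0.0952 to -0.067 at 48 h, from 0.05 to 0.0682 at 20 h against untreated, where fewer libraries raise the smallest p, and from -0.0403 to 0.0048 in H9 (reversed without fresh library 4). At 48 h against 20 h the difference in the WCpA ratio no longer passed 0.05 when any 1 of the 20 h libraries was left out, though the libraries still did not overlap. Strand values ran from -0.0069 to 0.0104 at 20 h against untreated, reversed without untreated library 4 and 20 h libraries 1 (-0.0023), 3 (-0.0068) and 4 (-0.0009), and from -0.026 to 0.0231 in H9, reversed without fresh library 4 and frozen library 1 (0.003). At 48 h log2 WCG calls ran from -0.0318 (library 2, reversed) to 0.0785 for amnion-like minus epiblast-like, -0.1209 (library 2, reversed; -0.0109 without library 3) to 0.1099 for amnion-like minus posterior streak-like and -0.0891 to 0.0314 (library 4, reversed) for epiblast-like minus posterior streak-like cells. Strand values there ran from -0.0836 to 0.009 (library 2, reversed) for amnion-like minus epiblast-like and -0.0134 (library 4, reversed) to 0.011 for Neuroectoderm-like minus posterior streak-like cells.

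Not run were the promoter windows, the start site enrichments, and the clustering resolution and variable genes, since the authors' types were used. A minimum of 3000 UMIs removed no cell and says nothing.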

Other observations

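The fits of cell types were planned, and the comparison of RNA content and the test of strand shares were chosen after the results were seen.

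Which genes the authors used to call the cell types is not given in the sources used here, so that the genes that follow are described without a claim that they are independent of the types. At 48 h posterior streak-like cells against the other types had COL5A1, a collagen, higher by 2.20 and HSPA8 by 0.67. Anterior streak-like cells had BNIP3 higher by 1.63, PGK1, a glycolytic enzyme, by 1.02 and DNMT3B by 1.38. Germ cell-like cells had EGR1 higher by 1.97 and DKK1 at -6.14, and amnion-like cells had the glucose carrier SLC2A1 at 1.52 and DNMT3B at -0.87. BMP targets were lower in epiblast-like cells in 10 of 12 at 20 h, 15 of 20 at 36 h and 7 of 19 at 48 h, with 0 higher in edgeR, and GATA2 and GATA3 are in both this list and the amnion list.

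Neuroectoderm-like cells held fewer UMIs than the other cells in every library of each arm, by log2 -0.705 at 20 h, -0.62 at 36 h, -0.578 at 48 h, -0.643 with CHIR99021 and -1.045 untreated. Per spike-in UMI the values were -0.544, -0.636, -0.58, -0.557 and -0.641, lower in every library but 1 of 3 untreated. At 48 h the medians averaged 20849.5 and 31402.9 UMIs. No test was made of a cause.

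In 1 cell of CHIR99021 library 3 the 5mC calls were unequal between strands, with plus shares of the autosomes from 0.335 to 0.664: 13 lay below 0.42, 6 between and 3 above 0.58. Its excess variance, times 1000, was 14.792, and the next highest were 2.851 at 48 h, 2.81 in the same library and 1.939 in library 4. In untreated cells the highest was 0.229, and above 1 were 3 of 113 treated cells, 1 of 264 at 48 h, 0 of 188 at 20 h, 0 of 90 untreated and 1 of 77 fresh H9 cells (1.117). The GpC calls of the same cell stayed within 0.028 of equal shares on every autosome, which argues against a strand bias of its sequencing library. No biological explanation was tested.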
